A study of Mus musculus with 12 samples.

How the data were processed

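The sources hold 12 libraries of total RNA from punches of BLA and VTA, 3 per group, with group, region and replicate taken from the sample titles and treatment labels and sex from the design text. Per the labels' protocols RNA was extracted with Trizol, and stranded libraries were made from 1 ug of RNA after depletion of ribosomal RNA. The deposited values are raw gene counts, for which the submitters' processing notes name cutadapt, TopHat2, HTSeq and the mm10 build, with no versions. The strand setting, the annotation and the handling of read mates are not given in the sources used here, so genes that overlap on opposite strands may share counts. A median of 1085 genes per library had a count of 1 and 2367 a count of 2.

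Each per-sample table held 54429 entries, and 53825 names (98.9%) matched gene names of the reference annotation for mm10. The table of the whole series differed from the per-sample tables at 2 entries, and the per-sample tables were used. Names of 26 entries had been turned into dates and 4 entries had repeated names. The 37 entries of mitochondrially encoded genes held 0 counts, so that list was not tested. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom of 20.8 or more over the 12 pairs).

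Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust dispersion), within each region on its 6 libraries. The difference of the responses, BLA minus VTA, was tested as a contrast on all 12. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05. Log2 fold changes are isolated relative to group-housed, and levels are TMM-scaled CPM, with factors over the 6 libraries of a region, or over all 12 libraries in the check of labels, in the difference and for Gh and Prl. Gene lists, 38 in all, covered stress response, neuronal activity, synapses, transmitters, immune response, metabolism and markers of cell types and neighbouring tissue. Of these, 36 were tested with camera (preset correlation 0.01, limma 3.58.1, log2 CPM with a prior count of 2), again with an estimated correlation, and with fry, and adjusted over the 36 lists.

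The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took up to 10 genes in each direction per region that passed the test with a mean of at least 1 CPM and groups that did not overlap. Where fewer passed, it was filled by the smallest p under the same 2 conditions. Separate groups in genes named this way are thus a condition of the choice, not a result. Without the condition on overlap, it took 5 genes per direction for the difference and up to 4 members of a list by smallest p. How many members of each list are described was settled after their values were seen: the first 2 by p in each called list and in a few others, and the first 4 where a list is treated at more length. Genes named because of a count of 5 or fewer, 3110053B16Rik for example, were chosen after their values were seen, as were Ttr, Slc17a7 and B2m, Nnt and the traces of other tissue. Some genes that the rule selects are not reported here. The list tests of the difference were added after the data were seen.

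The scripts were tested on simulated counts drawn from the real means and library sizes. The changed genes were taken only from those above a limit on mean count, and genes varied independently of each other. The shares recovered therefore do not cover genes of low count, or shifts that many genes share within a library. For BLA, run on 21605 genes, 34.3% of genes changed 1.5-fold, 77.3% changed 2-fold and 98.2% changed 4-fold were recovered. For VTA (23502 genes) these shares were 22.7%, 59.4% and 91.2%, and for the difference (24523 genes) 5.7%, 37% and 79.7%. False calls made up 12.8%, 12.1% and 9.4% of the calls in these simulations, averaged over 5 runs, above the nominal 5%. The limit on false calls that the test had to meet was loosened once, after an earlier run exceeded it.

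Alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile factors, no filter, a filter of 10 counts in 3 samples, a single fit of all 12 libraries, a replicate block, a threshold of 0.1 and leaving out each library. After the data were seen, fits without libraries rich in ribosomal RNA reads or in markers of other tissue were added, as were fits with those measures as covariates, for genes and, by linear regression over the 6 libraries of a region, for the mean log2 CPM of 4 lists. Figures were drawn with matplotlib 3.10.9.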

Results

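RNA from brain punches of C57BL/6 mice was sequenced in 12 libraries that form 4 groups of 3. The labels name the punched regions only as BLA and VTA. In the design text the BLA libraries come from males and the VTA libraries from females, and in each region mice isolated early in life were set against group-housed mice. Region and sex therefore change together, and no contrast between BLA and VTA separates them. Total counts per library ranged from 28278708 to 69276892. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

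The regions and sexes matched their labels. Slc6a3, the dopamine transporter, lay between 229.5 and 525.5 CPM (counts scaled to library size with TMM factors) in the VTA libraries and at most 1.09 CPM in the BLA libraries. Slc17a7, the vesicular glutamate transporter of cortical and amygdalar neurons, lay at 448.3 CPM or more in every BLA library. In the VTA libraries it ran from 2.87 CPM to 233 CPM, the highest being isolated library 3. Neurod6, another marker of such neurons, barely separated the regions. It lay at 23.57 CPM or more in the BLA libraries and at up to 20.44 CPM in the VTA libraries, again in isolated library 3. Xist, the RNA that silences an X chromosome in females, reached 134 CPM or more in every VTA library and at most 4.42 CPM in the BLA libraries. Ddx3y, a Y-linked helicase, lay at 73.5 CPM or more in every BLA library and at most 1.02 CPM in the VTA libraries.

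Libraries of one group were uneven in other ways. Lars2, CT010467.1 and Gm15564, loci that collect reads of ribosomal RNA, took 18.6% of the counts in isolated BLA library 3, 28.6% in group-housed BLA library 1 and 41.8% in group-housed BLA library 2, against at most 1.57% in the other libraries. Group-housed BLA library 2 was also the shallowest, with 28278708 counts before these loci are taken off.

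**Figure D1:**
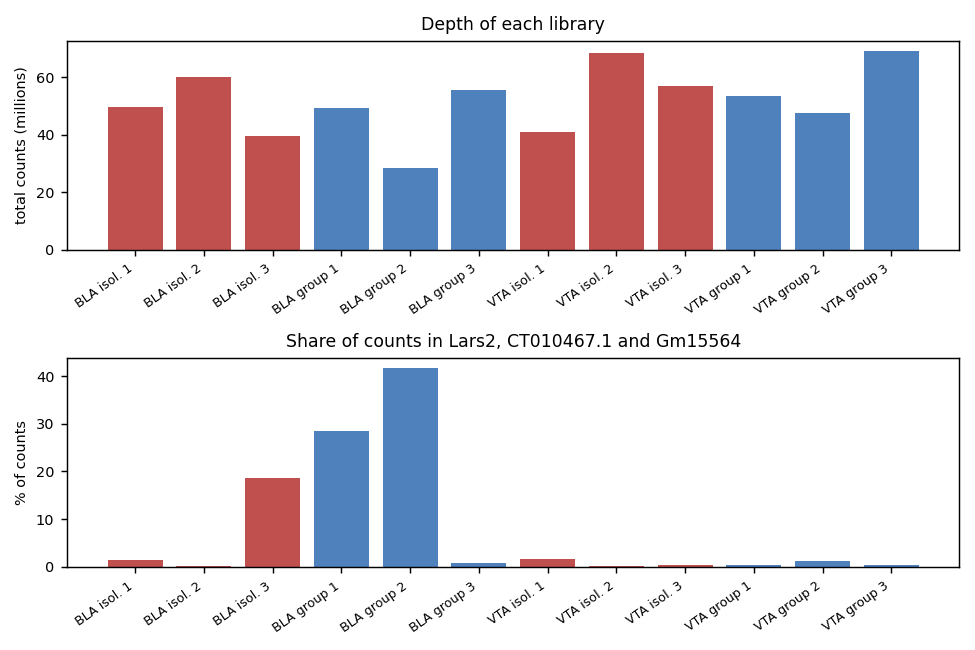
Total counts (upper bars) and the percentage of counts in Lars2, CT010467.1 and Gm15564 (lower bars) for each of the 12 libraries, isolated (isol.) in red and group-housed (group) in blue. Depth lay between 28278708 and 69276892 counts, and 3 BLA libraries held 18.6% to 41.8% of their counts in these loci.

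The first comparison asked which genes differ in the BLA between isolated and group-housed males. Immediate early genes, which neurons transcribe within minutes of activity, fell as a list in isolated BLA, with 22 of 24 measured members lower and a median log2 fold change of -0.34. Examples were Dusp6, a phosphatase that switches off ERK, at 40.7 ± 1.21 CPM against 51.6 ± 3.30 CPM (SD, n = 3 per group), and Fos, a subunit of the AP-1 transcription factor, at 10.9 ± 4.35 against 21.3 ± 8.69 CPM. Btg2, an antiproliferative gene, had a log2 fold change of -0.48 (SE 0.16) and Jun, another AP-1 subunit, -0.37 (SE 0.18). The camera test called the list at a Benjamini-Hochberg adjusted p = 1.72e-06, and at an adjusted p = 0.957 with an estimated correlation. No single member passed, over all genes or adjusted over the list alone (0 genes). Without the 3 libraries rich in ribosomal RNA reads, which leaves 1 group-housed library, the median of the list was -0.08.

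Genes of the interferon response also fell as a list, with 37 of 42 members lower and a median of -0.17 (camera, Benjamini-Hochberg adjusted p = 0.000328, and adjusted p = 0.957 with an estimated correlation). Ifi44, an interferon-induced gene, had a log2 fold change of -1.09 (SE 0.56) at under 1 CPM, and Ifitm3, an antiviral membrane protein, -0.40 (SE 0.21). In the same 3 remaining libraries, 1 of them group-housed, the interferon median was 0.08. Heat shock and unfolded protein response genes fell, with 21 of 25 members lower and a median of -0.10 (camera, Benjamini-Hochberg adjusted p = 0.025, and adjusted p = 0.957 with an estimated correlation). Hspa1b, an inducible HSP70 chaperone, had a log2 fold change of -1.05 (SE 0.36) and Manf, a protein induced by stress of the endoplasmic reticulum, -0.22 (SE 0.11). Without group-housed BLA library 3 the median of the heat shock list was -0.02. In none of these lists did a member pass, adjusted over the list alone (0 genes).

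Markers of neighbouring neuron types moved apart. Markers of cortical and basolateral glutamatergic neurons fell, 18 of 19 being lower with a median of -0.22 (camera, Benjamini-Hochberg adjusted p = 0.00476, and adjusted p = 0.957 with an estimated correlation), among them the transcriptional regulators Lmo3 at -0.34 (SE 0.20) and Emx1 at -0.30 (SE 0.19). Markers of striatal projection neurons rose, all 19 being higher with a median of 0.42 (camera, Benjamini-Hochberg adjusted p = 0.0271, and adjusted p = 0.957 with an estimated correlation), among them Ankk1 at 1.28 (SE 0.57) and the transcription factor Isl1 at 0.75 (SE 0.62). Without isolated BLA library 1 both medians changed sign, to -0.09 for the striatal and 0.02 for the glutamatergic markers. Without group-housed BLA library 3 the striatal median was 0.09 and the camera test gave the opposite direction.

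**Figure D2:**
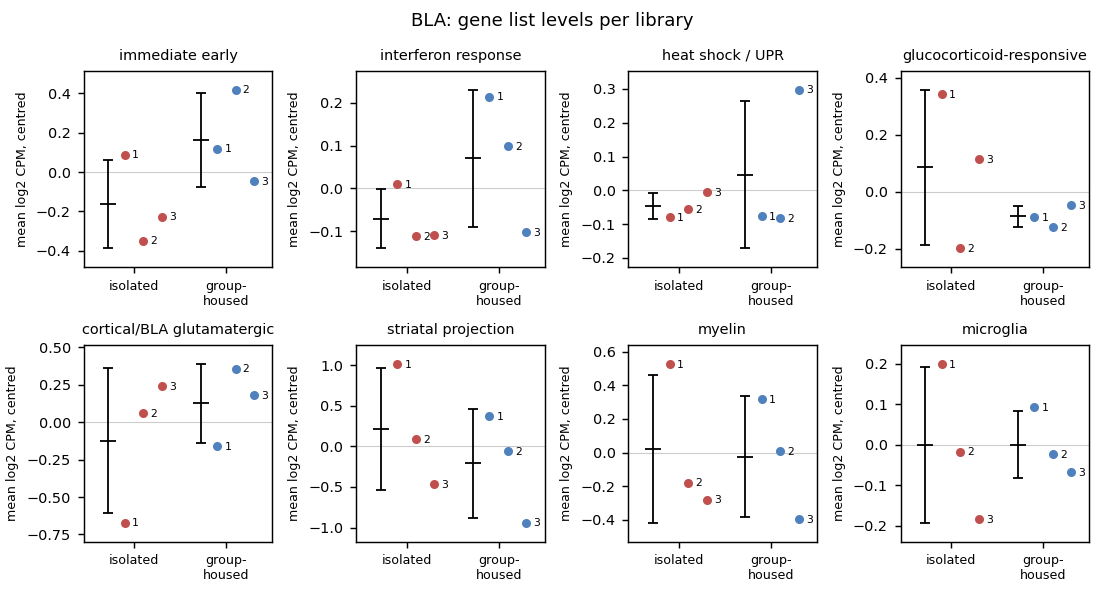
Mean log2 CPM of 8 gene lists in each BLA library, centred on the mean of the 6 libraries; points are libraries with their replicate number, bars the mean and SD of each group of 3. The ranges of the groups overlap in each of the 8 panels, and for the striatal markers isolated library 1 stands highest and group-housed library 3 lowest.

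A cluster of genes on chromosome 17 stood out among the smallest p-values, none of which passed the adjustment in the filtered edgeR fit. The class I histocompatibility genes H2-T22 (log2 fold change 0.88, SE 0.20), H2-T24 (0.96, SE 0.23) and H2-D1 (0.71, SE 0.18) were higher in isolated BLA, as was H2-T23 at 4.84 ± 1.42 against 1.65 ± 0.922 CPM (SD, n = 3 per group), and so were the ribosomal protein genes Rps2 (0.82, SE 0.15) and Rps18 (1.02, SE 0.23), the chromatin protein gene Hmga1 (0.50, SE 0.14) and the Wnt pathway gene Dact2 (0.39, SE 0.11). H2 genes and ribosomal protein genes have near-identical copies, so reads could be split among them and their values are uncertain. Adjusted over the list alone, 2 of 22 complement and antigen presentation genes (H2-D1 and H2-T23) and 1 of 79 ribosomal protein genes (Rps2) were called.

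Among the other genes named by the fixed rule, Wdfy1, an endosomal adaptor, had the smallest p and lay at 57.9 ± 1.15 CPM in isolated against 37.8 ± 2.94 CPM in group-housed BLA (SD, n = 3 per group), a log2 fold change of 0.61 (SE 0.09) with an edgeR, Benjamini-Hochberg adjusted p = 0.881. The pseudogene Zfp125 lay at 3.78 ± 2.20 against 0.461 ± 0.188 CPM. Lower in isolated BLA were Bc1, a noncoding RNA of dendrites (-0.63, SE 0.17), the transcription factor Klf10 (-0.39, SE 0.11), Rasl11a (-0.71, SE 0.21), Kctd13 (-0.30, SE 0.09), Snrpc, a protein of the U1 splicing particle (-0.32, SE 0.11), Fam149a (-0.41, SE 0.12), the galactosyltransferase B4galt3 (-0.27, SE 0.10) and Arid5a (-0.35, SE 0.12). All of these missed the threshold in the filtered edgeR fit.

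Of 22110 genes tested in BLA, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 at an adjusted p of 0.05, while 439 had an unadjusted p under 0.05 (1.99% of the genes). limma voom also called 0, and DESeq2 called 5, all higher in isolated BLA (Wdfy1, Zfp125, 3110053B16Rik, Rps2 and Rps18). Without the low-count filter edgeR called 8, among them Wdfy1, Zfp125, Rps2 and Bc1. Groups did not overlap at 7.1% of the genes, where chance gives 10%. Of 36 lists tested, 5 were called, and 0 with an estimated correlation or with fry's directional test. Without isolated BLA library 3 the count was 11, and without group-housed BLA library 3 it was 3. The other 31 lists had camera adjusted p-values from 0.0638 to 0.957, among them glucocorticoid-responsive genes, with 19 of 22 higher and a median of 0.12.

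The second comparison asked the same question for the VTA of females. Postn, which encodes the matricellular protein periostin, rose in isolated VTA, at 25.04 ± 0.898 CPM against 11.6 ± 0.450 CPM in group-housed VTA (SD, n = 3 per group). Its log2 fold change was 1.11 (SE 0.09), with an edgeR, Benjamini-Hochberg adjusted p = 0.0235, and each isolated library lay above each group-housed one. Postn lies on chromosome 3 from 54361109 to 54391037 (mm10). Leaving out any library other than isolated VTA library 2 ended the call (edgeR, Benjamini-Hochberg adjusted p from 0.0661 to 0.274), while its log2 fold change stayed between 1.08 and 1.15.

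**Figure D3:**
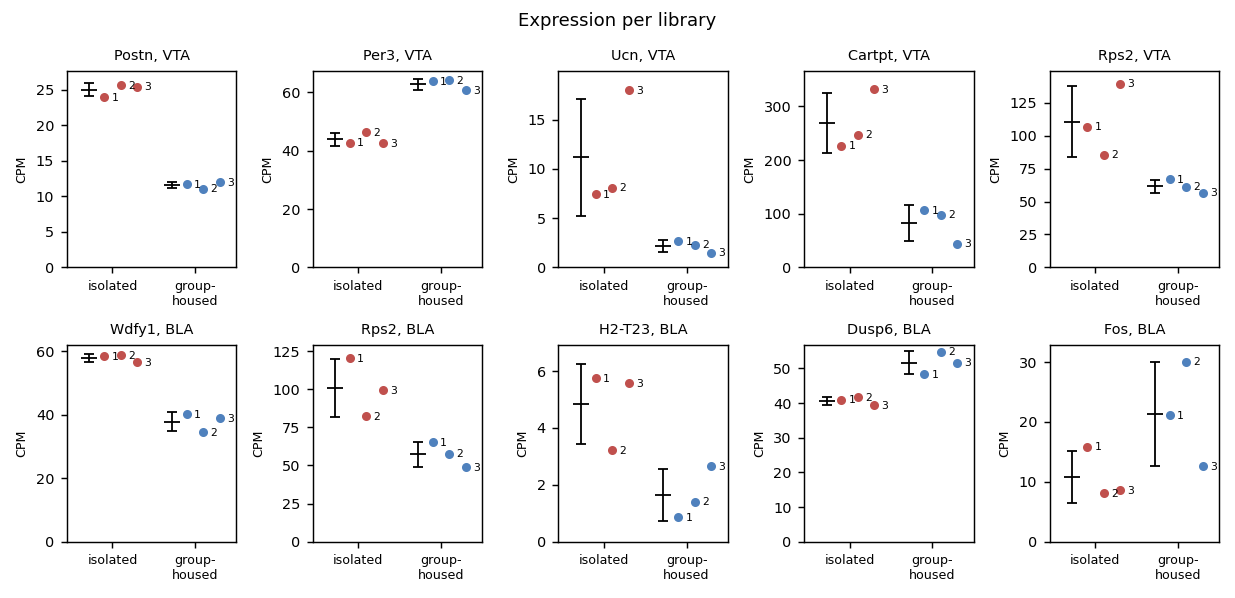
CPM of 10 genes per library in VTA (upper panels) and BLA (lower panels), isolated in red and group-housed in blue; points are libraries with their replicate number, bars the mean and SD of each group of 3. Postn in VTA lies near 25.04 CPM in isolated and near 11.6 CPM in group-housed libraries.

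Lists of cellular energy supply and protein synthesis were higher in isolated VTA, although no single member of either passed, over all genes or adjusted over the list alone (0 genes). Among nuclear-encoded subunits of oxidative phosphorylation, 72 of 73 were higher with a median log2 fold change of 0.27, and groups did not overlap at 35 of them, where chance gives 10% and all VTA genes showed 26.1% (camera, Benjamini-Hochberg adjusted p = 3.01e-16, and adjusted p = 0.614 with an estimated correlation). On the centred log2 scale the list lay at 0.229, -0.014 and 0.162 in isolated libraries 1, 2 and 3. Group-housed libraries 1, 2 and 3 lay at -0.201, -0.161 and -0.016, so isolated library 2 barely exceeded the highest of them. Atp5e, a subunit of ATP synthase, lay at 69.8 ± 7.16 against 50.8 ± 1.69 CPM and Uqcrfs1, the iron-sulfur protein of complex III, at 109 ± 6.08 against 90.5 ± 5.47 CPM (SD, n = 3 per group). Among cytosolic ribosomal proteins, 76 of 79 were higher with a median of 0.19 (camera, Benjamini-Hochberg adjusted p = 2.39e-13, and adjusted p = 0.614 with an estimated correlation), led by Rps2 at 0.85 (SE 0.17) and Rpl38 at 0.28 (SE 0.08). The mean level of the ribosomal list differed by 0.19 (SE 0.05), and by 0.11 (SE 0.06) with the cortical and 0.12 (SE 0.04) with the choroid plexus marker score as a covariate, against 0.25 (SE 0.09), 0.21 (SE 0.14) and 0.19 (SE 0.12) for oxidative phosphorylation. Random lists matched to the ribosomal list on gene length and expression had a median of 0.20, against its own 0.19. The draws could include genes of the list itself, so they cannot decide whether length and level account for it.

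Glucocorticoid-responsive genes, which stress hormone receptors switch on, rose with 21 of 22 higher, a median of 0.28 and groups that did not overlap at 13 (camera, Benjamini-Hochberg adjusted p = 1.24e-05, and adjusted p = 0.614 with an estimated correlation). Nfkbia, an inhibitor of NF-kB, had a log2 fold change of 0.44 (SE 0.10) and Tsc22d3, also known as GILZ, 0.38 (SE 0.10), and both were called when adjusted over the list alone. The mean level of this list differed by 0.33 (SE 0.13), and by 0.16 (SE 0.14) with the cortical and 0.21 (SE 0.14) with the choroid plexus marker score as a covariate. Immediate early genes rose with 21 of 24 higher and a median of 0.40 (camera, Benjamini-Hochberg adjusted p = 0.000394, and adjusted p = 0.614 with an estimated correlation), including Dusp6 at 0.44 (SE 0.13) and Fosl2 at 0.64 (SE 0.20). Isolated library 3 stood apart for this list (0.80 on the centred log2 scale, against 0.13 and -0.17 in the other isolated libraries and from -0.36 to -0.06 in the group-housed ones), and with the cortical or the choroid plexus marker score as a covariate the list was not called, at medians of 0.05 and 0.12. Heat shock and unfolded protein response genes rose with 23 of 25 higher and a median of 0.11 (camera, Benjamini-Hochberg adjusted p = 0.00748, and adjusted p = 0.614 with an estimated correlation), including the co-chaperone Dnajb1 at 0.36 (SE 0.09) and the transcription factor Atf4 at 0.22 (SE 0.09). Without isolated library 2 the heat shock list was not called, at a median of 0.06.

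Synaptic and channel lists were also higher, with isolated library 3 the highest library in each. The median was 0.22 for presynaptic vesicle release (40 of 44 higher), 0.27 for glutamate receptors and their scaffold (40 of 47), 0.19 for voltage-gated ion channels (42 of 53), 0.14 for GABA synthesis, transport and receptors (16 of 25) and 0.26 for dopamine receptors and signalling (11 of 15). Their camera, Benjamini-Hochberg adjusted p-values ran from 2.1e-05 to 0.045, and with an estimated correlation the adjusted p was 0.614 for each, except 0.658 for dopamine signalling. With the cortical marker score as a covariate none of the 5 was called and the medians were 0.14, -0.04, 0.06, 0.06 and -0.04 in the same order. With the choroid plexus score presynaptic release alone was called, at 0.14, and the others lay from 0.07 to 0.11. The GABA list was not called without isolated library 1 (0.13) or group-housed library 3 (0.12), nor dopamine signalling without isolated library 3 (0.19) or group-housed library 3 (0.34). Dnm1, the dynamin of synaptic vesicle recycling, had a log2 fold change of 0.58 (SE 0.12), Syn1, a synapsin, 0.80 (SE 0.22), and Shank1, a postsynaptic scaffold, 0.42 (SE 0.11). Kcnh7 lay at 0.34 (SE 0.09), the GABA-A receptor subunit gene Gabrb2 at 0.37 (SE 0.10), and the dopamine signalling genes Gnal and Pde1b at 0.43 (SE 0.13) and 0.34 (SE 0.11). The kainate receptor gene Grik4 went the other way at -0.35 (SE 0.09). Adjusted over the list alone, Dnm1 was called among the presynaptic genes.

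Markers of tissue outside the VTA moved with isolation too. Choroid plexus markers were higher in all 20 cases, with a median of 2.48 (camera, Benjamini-Hochberg adjusted p = 9.26e-05, and adjusted p = 0.658 with an estimated correlation). With the cortical marker score as a covariate the median of this list turned negative. Ttr, the abundant transthyretin of the choroid plexus, lay at 231 CPM in isolated VTA library 1, 3.16 CPM in library 2 and 3530 CPM in library 3, against 0.303 to 1.06 CPM in the group-housed libraries. Otx2, a transcription factor, had a log2 fold change of 0.94 (SE 0.34), and -0.03 without isolated libraries 1 and 3, which leaves 1 isolated library. Markers of cortical and basolateral glutamatergic neurons rose with 18 of 19 higher and a median of 1.14 (camera, Benjamini-Hochberg adjusted p = 2.58e-05, and adjusted p = 0.614 with an estimated correlation). Slc17a7 lay at 26.9, 9.60 and 264 CPM in the isolated libraries and from 3.46 to 6.19 CPM in the group-housed ones, while Nrn1, the neuritin gene, had a log2 fold change of 0.68 (SE 0.11) and Emx1 3.59 (SE 1.13) at under 1 CPM. Striatal projection neuron markers had 16 of 19 higher and a median of 0.52 (camera, Benjamini-Hochberg adjusted p = 0.0202, and adjusted p = 0.658 with an estimated correlation), including Ido1 at 1.30 (SE 0.47) and Syndig1l at 0.47 (SE 0.14). Isolated library 3 carried this list, at 1.16 on the centred log2 scale against -0.11 and -0.26 in the other isolated libraries and from -0.43 to -0.12 in the group-housed ones. Without isolated library 3 the list was not called, at a median of 0.13, nor without group-housed library 3, at 0.54.

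Glial lists rose too, with medians below those of the markers of other tissue just described. Myelin genes had a median of 0.29 (20 of 23 higher, with Tspan2 at 0.49, SE 0.14, and Mal at 0.48, SE 0.14), microglia markers 0.26 (all 23 higher, with Selplg at 0.38, SE 0.18) and astrocyte markers 0.10 (16 of 19 higher, with the transporters Slco1c1 at 0.42, SE 0.14, and Slc1a2 at 0.29, SE 0.10). Camera, Benjamini-Hochberg adjusted p-values were 0.000198, 0.00196 and 0.0179, and with an estimated correlation the adjusted p was 0.658, 0.692 and 0.614. With the cortical marker score as a covariate the microglia median was -0.10, and without isolated library 3 that list was not called, at 0.10. Astrocyte markers were not called without isolated library 2 (0.07) or group-housed library 1 (0.08).

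**Figure D4:**
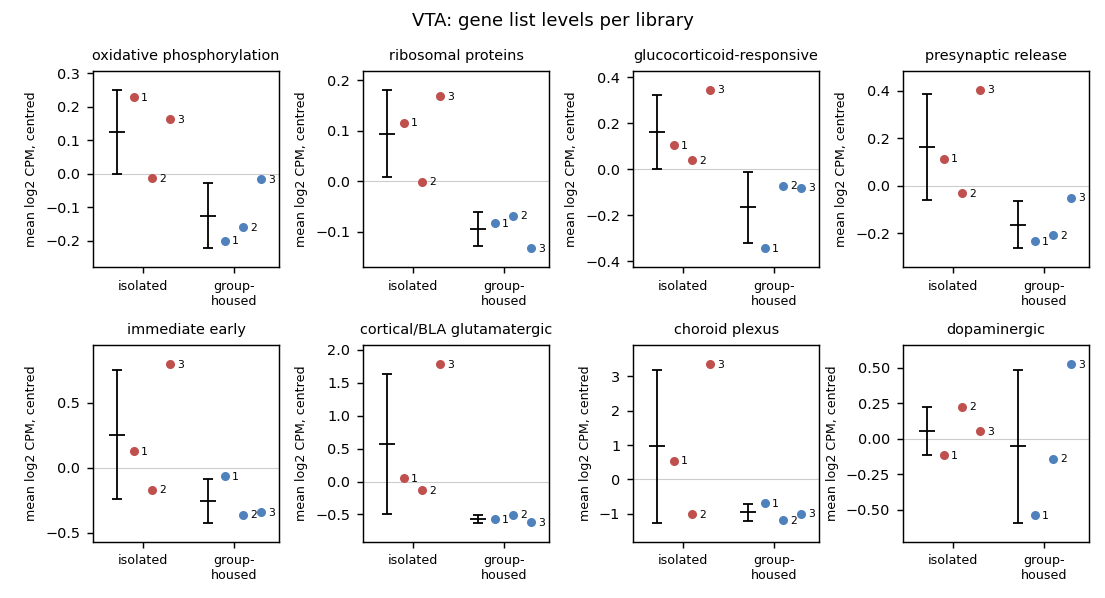
Mean log2 CPM of 8 gene lists in each VTA library, centred on the mean of the 6 libraries; points are libraries with their replicate number, bars the mean and SD of each group of 3. Isolated library 3 stands highest for the cortical and choroid plexus markers, and isolated library 2 is the lowest isolated library in 7 of the 8 panels.

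Dopaminergic neuron markers, the cells that define the VTA, did not pass (median 0.06, 11 of 20 higher, camera, Benjamini-Hochberg adjusted p = 0.257), with Nr4a2 at 0.62 (SE 0.16) and Foxa2 at 0.66 (SE 0.28). Neuropeptide genes went both ways and did not pass (median 0.03, camera, Benjamini-Hochberg adjusted p = 0.817). Ucn, the urocortin gene of the corticotropin-releasing factor family, lay at 11.2 ± 5.91 against 2.15 ± 0.602 CPM, Cartpt, the CART peptide precursor, at 269 ± 55.8 against 83.0 ± 33.6 CPM (SD, n = 3 per group), and Cck, the cholecystokinin gene, had a log2 fold change of 1.04 (SE 0.34). The list of neighbour markers did not pass either (camera, Benjamini-Hochberg adjusted p = 0.14). Its members with the smallest p were Otp, a homeobox factor (-2.03, SE 0.34), Calb2, the calretinin gene (0.37, SE 0.09), Hcrt, the orexin precursor (-5.04, SE 1.32, at 8.03 ± 9.63 CPM in the group-housed libraries) and Agrp (-0.95, SE 0.37). Of the clock genes, Per3 was lower at 43.9 ± 2.14 against 62.8 ± 1.86 CPM (log2 fold change -0.52, SE 0.07) and Hlf higher at 0.37 (SE 0.09). Both were called when adjusted over the list alone, as were Ucn, Otp and Calb2 in their lists, while Hcrt and Agrp were not.

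Further genes named by the rule shared an edgeR, Benjamini-Hochberg adjusted p = 0.236 and did not pass. Higher in isolated VTA were Atp6v0c, a subunit of the vesicular proton pump (0.66, SE 0.10), the transcription factor Foxp2 (0.53, SE 0.09), C1ql1, a secreted synaptic organiser (1.03, SE 0.17), the phosphatase Acp1 (0.48, SE 0.08), the neuronal calcium sensor Vsnl1 (0.52, SE 0.09) and the adhesion molecule Cadm2 (0.48, SE 0.09). Lower were the protocadherin Dchs1 (-0.60, SE 0.09), Spaca6 (-0.93, SE 0.15), the transcription factor Pax3 (-1.90, SE 0.34), Greb1l (-0.73, SE 0.14), Safb2 (-0.54, SE 0.11), the peptidase Ece2 (-0.93, SE 0.18) and the potassium channel gene Kcnt1 (-0.39, SE 0.08).

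Of 24082 genes tested in VTA, edgeR's quasi-likelihood test called 1, while 4408 had an unadjusted p under 0.05 (18.3% of the genes) and groups did not overlap at 26.1%, where chance gives 10%. DESeq2 called 450 (129 higher, 321 lower), limma voom 2, and edgeR with upper-quartile factors 0. Without isolated VTA library 2 edgeR called 1200 (370 higher, 830 lower), and without any other library 0. The fit with 1200 calls keeps isolated libraries 1 and 3, the highest in choroid plexus markers. That list lay at 0.54 and 3.36 in them on the centred log2 scale, against -1.02 in library 2. Of 36 lists, 16 were called, all higher, and 0 with an estimated correlation or with fry's directional test, while fry's mixed test called 1 (oligodendrocyte precursor markers). No member of the 16 lists passed over all genes. With the cortical or the choroid plexus marker score as a covariate 7 and 8 lists were called, and with the cortical score the striatal markers had a median of -0.19. The other 20 had camera adjusted p-values from 0.0573 to 0.96.

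The third comparison asked whether the response to isolation differed between male BLA and female VTA. Immediate early genes had medians of -0.34 in BLA and 0.40 in VTA and a median difference of -0.78 (camera, Benjamini-Hochberg adjusted p = 2.31e-06, and adjusted p = 0.655 with an estimated correlation). The VTA median of this list was 0.05 with the cortical and 0.12 with the choroid plexus marker score as a covariate. Oxidative phosphorylation genes had medians of 0.02 in BLA and 0.27 in VTA, a median difference of -0.28 (camera, Benjamini-Hochberg adjusted p = 5.86e-10, and adjusted p = 0.655 with an estimated correlation). In all, 14 of 36 lists were called, each lower in BLA relative to VTA, and 0 with an estimated correlation or with fry's directional test. The medians of microglia, myelin and choroid plexus markers turned positive when 5 libraries were left out. That fit leaves 1 group-housed BLA and 1 isolated VTA library.

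No gene passed. The smallest p belonged to Eif2s3y (difference -1.73, SE 0.25, edgeR, Benjamini-Hochberg adjusted p = 0.093), a Y-linked gene present in female VTA at 0.272 to 0.435 CPM in isolated and 0.0952 to 0.133 CPM in group-housed libraries, near the floor of detection. Dusp6 (-0.85, SE 0.16), Spry4, which like Dusp6 restrains ERK signalling (-0.86, SE 0.18), C1ql1 (-1.58, SE 0.30) and Gfod1 (-0.54, SE 0.11) lay lower in BLA relative to VTA. Per3 (0.70, SE 0.11), Spaca6 (1.06, SE 0.20), the receptor gene P2ry14 (1.18, SE 0.27) and Rgs11, a regulator of G-protein signalling (1.16, SE 0.26), lay higher. Of 25009 genes, edgeR called 0 and limma voom 0, DESeq2 called 127 (99 higher, 28 lower) and 3729 had an unadjusted p under 0.05. Without isolated VTA library 2 edgeR called 487, and without isolated VTA library 1 it called 1 (Eif2s3y).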

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

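The counts over other splits of the libraries were planned, and every other test in this part, with the list tests of the difference, was chosen after the result was seen. Tests of a list's mean level with a covariate replaced 2 earlier ones. In the first, camera with the same covariates, each of the 4 lists stayed called, but at the preset correlation, while with an estimated correlation none was called even without a covariate (adjusted p = 0.614 in VTA and 0.957 in BLA). The second left out libraries and rested on 1 library of a group.

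A test of the difference between the responses of BLA and VTA called 14 lists with camera at the preset correlation, each with a negative median difference (BLA minus VTA), and 0 with an estimated correlation (adjusted p of 0.655 or more for each). The medians were -0.78 for immediate early genes, -0.28 for glucocorticoid-responsive genes, -0.35 for glutamate receptors, -0.20 for GABA genes, -0.36 for presynaptic release, -0.23 for voltage-gated ion channels and -0.28 for heat shock genes. They were -0.27 for microglia, -0.18 for astrocyte, -0.36 for myelin, -2.19 for choroid plexus and -1.44 for cortical and basolateral glutamatergic markers, -0.28 for oxidative phosphorylation and -0.18 for ribosomal proteins. The microglia, myelin and choroid plexus medians turned positive when 5 libraries were left out, a fit with lone libraries in some groups. Region and sex were not separated. Of 100 splits of the 12 libraries, 34 gave at least 14 lists, the highest other split giving 24, so chance was not excluded. For genes, the real split called 0 and the highest other 41. With a real count of 0 all 100 of the 100 splits give as many by construction, which says nothing about chance. The real split had 3729 genes with an unadjusted p under 0.05. The highest other split, at 4695, kept the real VTA groups and regrouped BLA alone, so it still held the VTA difference. Among the splits that mixed the VTA groups the highest had 2967.

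Within a region there are 10 splits, too few for a share under 0.05. In BLA the real split called 0 genes and the highest other 2, and with a real count of 0 all 10 give as many by construction. It called 5 lists and the highest other 14, and 7 of 10 gave as many. In VTA the real split called 1 gene and the highest other 0, so 1 of 10 gave as many, and it called 16 lists against at most 19, with 4 of 10 giving as many. Genes with an unadjusted p under 0.05 numbered 439 in the real BLA split and 1803 in the highest other, and 4408 in the real VTA split and 2702 in the highest other.

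The first pattern is the rise of many lists in isolated VTA, for which tissue from outside the VTA in isolated libraries 1 and 3 is a candidate explanation drawn from the marker lists themselves: library 3 but not library 2 lay above the group-housed libraries in 2 of 3 lists of such tissue (choroid plexus and striatal), while in the cortical list library 2 did so too, and lists that gave rise to the explanation cannot test it. Between the libraries, the mean level of the oxidative phosphorylation list differed by 0.252 (SE 0.092). With the cortical score as a covariate it differed by 0.211 (SE 0.140), and with the choroid plexus score by 0.193 (SE 0.119). That of the glucocorticoid-responsive list differed by 0.328 (SE 0.129), and by 0.155 (SE 0.141) and 0.205 (SE 0.143) with these covariates. For these 2 lists isolation and such tissue cannot be told apart, the spread of 6 libraries being too wide. The ribosomal list fell from 0.189 (SE 0.054) to 0.114 (SE 0.056) and 0.120 (SE 0.040), each still more than 2 SE. With 3 residual degrees of freedom a limit of 2 SE is loose, so such tissue as its whole cause is not excluded either. Random lists matched on gene length and expression level had medians of 0.20 for oxidative phosphorylation and 0.11 for glucocorticoid-responsive genes. The lists' own 0.27 and 0.28 lay above the upper limits of 0.23 and 0.18 that most matched lists kept to. For ribosomal proteins the matched median was 0.20, against the list's own 0.19. The draws could include a list's own genes and took genes independently. Genes of a list vary together (estimated correlation 0.714 for oxidative phosphorylation and 0.315 for glucocorticoid-responsive genes), so these limits are too narrow. The draws therefore cannot decide whether length and level account for any of the 3 lists. Postn kept a log2 fold change of 1.11 (SE 0.11) with the choroid plexus score as a covariate, against 1.11 (SE 0.09) without, although its call ended (edgeR, Benjamini-Hochberg adjusted p = 0.109, from 0.0212 to 0.274 over its edgeR alternatives without a library) with fewer residual degrees of freedom. An effect of isolation on these genes stays open, as does a difference in dissection that the marker scores do not capture.

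The second pattern is the lower immediate early genes in isolated BLA. With the striatal score as a covariate the mean level of the list differed between the groups by -0.416 (SE 0.173), more than 2 SE. The difference thus did not shrink with this score. With 3 residual degrees of freedom a limit of 2 SE is loose, so striatal tissue in some punches as the whole cause is not excluded. The share of ribosomal RNA reads cannot be told apart from isolation here: with the log2 share as a covariate the difference was -0.234 (SE 0.209), against -0.325 (SE 0.188) without, so the spread of 6 libraries leaves it open. Across the 6 BLA libraries the list's level correlated with the log2 share at r = 0.624 (exact permutation p = 0.196) and rho = 0.829 (exact permutation p = 0.0583), and at r = -0.143 without the 2 libraries farthest from the median share, so the relation rests on those libraries. Isolation, and handling of the mice before collection, stay open and untested.

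The third pattern is that 9 of the 51 BLA genes with an unadjusted p under 0.01 lay on chromosome 17, where 2.18 were expected, all 9 higher in isolated BLA and between 14.2 and 36 Mb. The shared direction holds under this cut only. In the same stretch Snrpc (-0.32, SE 0.11, edgeR unadjusted p = 0.0143) and Hspa1b (-1.05, SE 0.36, edgeR unadjusted p = 0.017) were lower in isolated BLA. More immune or endothelial cells are argued against, since the microglia median was 0.022, the endothelial median -0.05 and B2m, the partner chain of class I molecules, lay at -0.35 (SE 0.20). For a mix of the J and N substrains of C57BL/6, Nnt, disrupted in the J substrain, lay at 0.092 (SE 0.098), so the groups hardly differed there. Nnt is not among the 9 genes, so its level cannot decide whether they differ through such a mix. A segment of chromosome 17 that differs between animals cannot be told apart from isolation: over the 6 VTA libraries the other genes of the segment correlated with its H2 genes at 0.149 on average, between the median of random genes (-0.006) and the upper limit that most of them kept to (0.259). Reads shared between H2 genes, or between ribosomal protein genes and their pseudogenes, were not tested.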

How the results depend on the processing

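Fits that leave out the libraries rich in ribosomal RNA reads or markers of other tissue, the marker and share covariates, and all list alternatives of the difference were chosen after seeing the data. The cause was not tested for any change below, except that fits without libraries or with covariates have fewer residual degrees of freedom, and unfiltered fits test more genes. Fits without the rich BLA libraries leave 1 group-housed BLA library, those without VTA libraries 1 and 3 leave 1 isolated VTA library, and those without 5 libraries both, each lone library being assumed to vary like the other groups.

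Genes called in BLA (0) numbered 5 with DESeq2, 8 without a filter and 1 without the 3 libraries rich in ribosomal RNA reads (Sim1), and from 0 to 4 leaving out each library (4 without isolated library 2). Genes called in VTA (1) numbered 450 with DESeq2, 2 with limma voom (Postn and Gh), 17 without a filter, 0 with upper-quartile factors, 0 without isolated libraries 1 and 3, 0 with the cortical or choroid plexus score as a covariate, and from 0 to 1200 leaving out each library (1200 without isolated library 2). A single fit of all 12 libraries called 1, Eif2s3y and not Postn. For the difference (0) DESeq2 called 127, a fit with no filter 1, a threshold of 0.1 called 1, and leaving out each library from 0 to 487. RLE factors and the stricter filter left these 3 counts as they were.

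Lists called in BLA (5) numbered 0 with an estimated correlation, 0 with fry's directional test, 8 without the rich libraries, 3 with the striatal score, and from 3 to 11 leaving out each library (11 without isolated library 3, 3 without group-housed library 3). In VTA (16) they numbered 0 with an estimated correlation, 0 with fry, 7 with the cortical and 8 with the choroid plexus score, 11 without libraries 1 and 3 and from 13 to 21 leaving out each library. For the difference (14) they numbered 0 with an estimated correlation, 0 with fry, 10 without 5 libraries and from 11 to 15 leaving out each library.

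Medians that changed sign, or whose test did, were 0.077 for the BLA interferon list without the rich libraries, and, leaving out each BLA library, from -0.093 to 0.693 for striatal and from -0.368 to 0.018 for glutamatergic markers. In VTA the microglia median was -0.063 without libraries 1 and 3, where Otx2 lay at -0.034. It was -0.102 with the cortical and -0.026 with the choroid plexus score. The cortical score also gave -0.035 for glutamate receptors, -0.039 for dopamine signalling, -0.30 for choroid plexus and -0.19 for striatal markers, the last being -0.006 with the choroid plexus score. For the difference, leaving out 5 libraries gave 0.20 for microglia, 0.44 for myelin and 0.70 for choroid plexus markers.

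Libraries of the same number deviated together in 1 of 3 pairs in BLA (correlation 0.425) and in none in VTA (at most 0.017). Libraries of different numbers reached 0.307 in BLA and 0.208 in VTA. With 3 libraries per group this check cannot decide whether the numbers pair them. With the replicate block the counts were 0 genes and 9 lists in BLA, 0 genes and 17 lists in VTA, and 1 gene (Emx1) and 13 lists for the difference.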

Other observations

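The test of the neighbour markers in this part was chosen after the result was seen.

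Serotonergic markers were lower in isolated VTA in 6 of 6 genes (median -0.69, camera, Benjamini-Hochberg adjusted p = 0.219), and Tph2, the enzyme of serotonin synthesis, lay at 109.5 CPM in group-housed VTA library 3 and at most 7.22 CPM in the other libraries. Pmch, the melanin-concentrating hormone precursor of the lateral hypothalamus, lay at 44.6 and 62.3 CPM in group-housed VTA libraries 1 and 2 and at most 5.35 CPM in the others.

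That punches of the 2 groups lay at different positions is a candidate explanation. Of 23 neighbour markers measured, 4 were lower in every isolated library than in every group-housed one and 1 was higher. Chance gives 10% in all, and all VTA genes showed 26.1%. A difference in position could separate other genes too, so the share over all genes cannot count against it and the markers do not decide. Position and isolation cannot be told apart here, since no label records the position of a punch.

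Rps2 was higher in isolated mice of both regions, at 101 ± 19.2 against 57.3 ± 8.33 CPM in BLA and 111 ± 27.1 against 61.6 ± 5.08 CPM in VTA (SD, n = 3 per group), and was called in neither by edgeR's filtered fit of all 6 libraries. It was called in BLA by edgeR without the low-count filter, in VTA by edgeR without isolated library 2, and in both by DESeq2. The VTA fit without isolated library 2 keeps the isolated libraries highest in choroid plexus markers. Of the 9 chromosome 17 genes higher in isolated BLA, 6 were higher in isolated VTA, and for 2 of these the groups did not overlap. Gh and Prl, hormone genes of the pituitary, lay at 0.302 to 0.819 and 0.617 to 2.69 CPM in the isolated VTA libraries. In the group-housed VTA libraries Gh had 0 counts and Prl lay at 0.0481 to 0.0589 CPM. Each isolated VTA library, library 2 included, thus held more of both.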
